A study of Homo sapiens with 8 samples.

How the data were processed

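The study hybridised total RNA from the human glioma lines LN229 and GBM8401 to OneArray gene microarrays, with 1 dye (Cy5) per array. The cells were kept in DMEM with 2% fetal bovine serum, and the RNA was extracted with Trizol after 48 hr with 10 microM momordicine or with DMSO. The deposited values are probe intensities on a linear scale. Every array has the same median and a lowest value, or floor, of 50. This was read from the values, since the scanner, the background correction and the normalization method are not given in the sources used here. The submitters' processing notes name limma, without a version. The plan had assumed log2 values; the values proved linear, so log2(intensity + 1) was taken, as the plan provided, with no further normalization between arrays. No detection calls were used.

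The table held 28264 probes. Of these, 25893 had 1 gene symbol and 0 had several, and the 2371 with none were left out except in a setting that tested every probe. All 25893 gene identifiers matched the reference table of genes, and 0 symbols were updated. For each of the 19090 genes, the probe with the highest mean log2 intensity over the 8 arrays was tested; 5751 genes had more than 1 probe. At the floor on all 8 arrays lay 4012 genes (21.0%), and no filter was applied. The median log2 level over genes and arrays was 8.17, an intensity of 287. Arrays have no read depth, and their number, 2 per group, limits the precision.

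The 8 arrays were fitted together in limma 3.58.1 under R 4.3.3, with the means of the 4 groups as coefficients, and tested by lmFit and eBayes with an intensity trend (residual degrees of freedom 4, prior degrees of freedom 0.72). The comparisons were momordicine against DMSO in each line, the mean of these effects, their difference (GBM8401 minus LN229), and the DMSO groups of the lines. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes, with 0.05 as the threshold. The replicate numbers were not used as blocks: the deviations of same-numbered arrays from their group means correlated at -0.11 in LN229 and 0.0990 in GBM8401. Where all arrays of a control group lay at the floor, a fold is given as a lower bound against 50.

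Before the data were examined, 48 gene lists were fixed for pathways, complexes and cell types. The 47 with at least 5 measured members were tested with camera, which compares a list with all other genes. It was run at a preset correlation of 0.01 and with adjustment over the lists. The list not tested held 13 mitochondrially encoded genes, of which 0 were measured. Camera with the correlation estimated for each list, and fry, which asks whether the members move one way on balance, were run as alternatives. With an estimated correlation, calls were lost even where the estimate lay below the preset value. Heat shock genes in LN229 had -0.000118 and metallothioneins -0.00402, yet adjusted p rose from 3.78e-06 to 0.0636 and from 0.00493 to 0.152. Other lists had higher estimates, such as 0.107 for complex I. A call lost this way does not by itself show that correlation between genes explains the list. Counts adjusted over the list alone use the members' p-values only. Genes were named by a rule fixed in advance. For each treatment comparison these were the 8 largest rises and 8 largest falls among genes past the threshold, with both treated arrays on one side of both control arrays and the higher group above the median level. To them came the 2 members with the lowest p-values among those that moved in the list's direction, for each list that passed. The named members of such a list thus share its direction by rule. For each list of the series' themes, the 2 members with the lowest p-values were taken in either direction. For the other comparisons the rule took 5 genes in each direction and, between the lines, the called cell type markers. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

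The fit was tested on simulated data with changes added to 67, 67 and 66 genes above the median level, at log2 sizes of 0.5, 1 and 2. It called 20.9%, 70.1% and 92.4% of them for LN229, 23.9%, 74.6% and 93.9% for GBM8401 and 47.8%, 86.6% and 100% for the mean effect. For the difference of effects the shares were 5.97%, 41.8% and 81.8%, and between the DMSO groups 22.4%, 62.7% and 95.5%. False calls made up 4.69%, 3.76%, 11.4%, 5.49% and 6.98% of the calls in these comparisons, in that order. The list test called a list shifted by -0.3 (adjusted p = 5.1e-30) and 0 of 46 unshifted lists. The simulated noise was independent between genes, and all other genes were left unchanged. No dimmer gene was given a change, so the shares called do not cover such genes. In the data 6810 genes passed in LN229, and the complex I list had an estimated correlation of 0.107. The simulated shares therefore need not carry over to the data, and the list run cannot show how often lists of correlated genes are called.

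The alternatives tried were quantile normalization, centring on the median of all or of the brighter genes, filters on dim genes, the mean of a gene's probes or every probe, pseudocounts of 0 and 16, and eBayes without trend or robust. Further ones were array weights, the spread from the compared arrays only, replicate blocks, leaving out each array, a 2-fold minimum, an adjusted p under 0.01, and unadjusted p with the 2-fold minimum. Of these, the filter on genes at the floor everywhere, the centring on brighter genes, the omission of the pseudocount and a crossed block were chosen after seeing the data, as were camera on the difference between the lines and on gene families, the checks of MYC, and the ratios of the effects of the lines under other scalings.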

Results

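Gene expression was measured on 8 one-colour microarrays in 2 human glioma cell lines, LN229 and GBM8401. Cells of each line were treated for 48 hr with 10 microM Momordicine I, a cucurbitane-type triterpenoid of bitter melon, or with the solvent DMSO, which gave 4 groups of 2 arrays. All 8 arrays had a median intensity of 207.775, and 25.9% to 31.7% of the probes of an array lay at the lowest value, 50. Intensities are means ± SD of the 2 arrays of a group (n = 2), and changes are log2 differences ± standard error (SE). The treatment set the arrays apart more than the line did. Pearson's r across genes, which are not independent replicates, was 0.992 to 0.996 within a group and 0.977 to 0.984 between the lines under the same treatment. Between the treatments within a line it was 0.869 to 0.894. The first principal component held 83.1% of the variance and separated treated from control arrays, and the second held 8.25% and separated the lines. The p-values measure only the spread between these arrays, because the labels do not say whether the 2 arrays of a group came from separate cultures.

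The series asks how glioma cells respond to the compound, with growth inhibition, apoptosis and mitochondrial oxidative phosphorylation (OXPHOS) as its themes. In LN229, treatment lowered the genes of cell division most. DLGAP5, a spindle assembly protein, (probe PH_hs_0004483) fell 85.9-fold (log2 change -6.42 ± 0.07 SE, adjusted p = 7.24e-06), from an intensity of 10841 ± 51.4 to 125 ± 7.30. SPC25, a kinetochore protein, fell 69-fold (log2 change -6.11 ± 0.14 SE, adjusted p = 3.68e-05), and the topoisomerase TOP2A fell 53.8-fold (log2 change -5.75 ± 0.09 SE, adjusted p = 1.41e-05). DDIT3, which encodes the transcription factor CHOP, went from 517 ± 20.0 to 16076 ± 402, a rise of 31.1-fold (log2 change 4.96 ± 0.09 SE, adjusted p = 2.23e-05). In all, 6810 of 19090 genes passed the limma test, 3442 higher and 3368 lower, and 2260 of them changed at least 2-fold.

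Among the largest rises in LN229 were those of the dopamine receptor gene DRD5, by at least 112-fold (log2 change 6.78 ± 0.09 SE, adjusted p = 1.16e-05), and INHBE, an inhibin and activin subunit (probe PH_hs_0032455), by 78.7-fold (log2 change 6.30 ± 0.15 SE, adjusted p = 4.07e-05). DRD5 lay at the lowest value on both control arrays, so its fold is a lower bound. The stress-induced chromatin protein gene NUPR1 rose 55.8-fold (log2 change 5.80 ± 0.12 SE, adjusted p = 2.88e-05). ANKRD22 rose at least 42.2-fold, OSCAR, an immunoglobulin-like receptor of osteoclasts, 33.2-fold, the peptide hormone gene SPX 32.5-fold and ANKFN1 29.8-fold. ANKRD22 lay at the lowest value on both control arrays, and OSCAR (60.3 ± 0.0700) and ANKFN1 (68.0 ± 22.7) lay near it. Among the other large falls were PIMREG at 67.9-fold, to 53.6 ± 2.05, near the lowest value, the spindle pole gene ASPM at 61.5-fold, the ribonucleotide reductase subunit RRM2 at 54.0-fold and CDC20, an activator of the anaphase-promoting complex, at 52.3-fold.

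Cell cycle genes fell as groups in LN229. Of the G2/M and mitosis genes, 64 of 66 fell and 0 rose (64 fell when adjusted over the list alone; median log2 change -4.25, adjusted p = 2.63e-40, adjusted p = 0.0363 with an estimated correlation). HMMR fell 42.2-fold (log2 change -5.40 ± 0.05 SE, adjusted p = 3.93e-06) and the spindle checkpoint kinase gene TTK 27.8-fold (log2 change -4.80 ± 0.05 SE, adjusted p = 5.49e-06). Of the genes of G1/S and DNA replication, 45 of 50 fell (45 adjusted over the list alone; median log2 change -2.59, adjusted p = 4.5e-24, adjusted p = 0.12 with an estimated correlation). The replication factor MCM10 fell 37.3-fold and thymidylate synthase, TYMS, 15.8-fold. Of the DNA repair genes, 16 of 23 fell (16 adjusted over the list alone; 1 rose, median log2 change -1.53, adjusted p = 5.54e-08, adjusted p = 0.0636 with an estimated correlation). BRCA1 fell 6.26-fold and its partner BARD1 5.86-fold. Of the lists tested in each line, the G2/M list alone passed with an estimated correlation, in LN229 and in GBM8401.

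The lists of ATF4, NRF2, unfolded protein response and metallothionein genes rose in LN229. Of the targets of ATF4, the transcription factor of the integrated stress response, 37 of 44 rose (38 adjusted over the list alone; 1 fell, median log2 change 1.38, adjusted p = 2.67e-15, adjusted p = 0.148 with an estimated correlation). SLC7A11, the cystine transporter that is also in the NRF2 list, rose 5.91-fold (log2 change 2.56 ± 0.04 SE, adjusted p = 1.37e-05), from 3102 ± 106 to 18332 ± 81.4. Of the NRF2 genes, which act in the oxidative stress response, 15 of 26 rose (15 adjusted over the list alone; 1 fell, median log2 change 0.74, adjusted p = 1.91e-05, adjusted p = 0.148 with an estimated correlation). Heme oxygenase 1, HMOX1, rose 8.55-fold (log2 change 3.10 ± 0.08 SE, adjusted p = 4.72e-05). Of the unfolded protein response genes, 16 of 31 rose (18 adjusted over the list alone; 1 fell, median log2 change 0.49, adjusted p = 0.00019, adjusted p = 0.268 with an estimated correlation). The ubiquitin ligase SYVN1 rose 2.12-fold and its partner SEL1L rose 3.36-fold. Another bright probe of SEL1L gave a log2 change of -0.48 in LN229 (adjusted p = 0.14), so the direction of SEL1L rests on its probe. Metallothioneins, which bind metal ions, rose at 6 of 8 genes (6 adjusted over the list alone; median log2 change 0.80, adjusted p = 0.00493, adjusted p = 0.152 with an estimated correlation). The named ones, MT1X at 8.05-fold and MT1G at 3.03-fold, have close relatives that probes may not tell apart, and MT1G lay near the lowest value in controls (63.3 ± 0.0350).

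Not every stress list rose in LN229. Heat shock genes fell at 15 of 22 members (16 adjusted over the list alone; 1 rose, median log2 change -0.61, adjusted p = 3.78e-06, adjusted p = 0.0636 with an estimated correlation). The chaperone HSP90AA1 fell 2.10-fold and HSPA1A, which has a nearly identical copy, 2.66-fold. The other antioxidant enzymes did not pass (4 of 18 up and 6 down; 5 and 6 adjusted over the list alone, median log2 change 0.01, adjusted p = 0.975, adjusted p = 0.981 with an estimated correlation).

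Interferon-stimulated genes rose in LN229 at 32 of 39 genes (33 adjusted over the list alone; median log2 change 1.70, adjusted p = 5.13e-14, adjusted p = 0.0722 with an estimated correlation). The antiviral gene RSAD2 was at the lowest value on both control arrays and rose at least 14.6-fold (log2 change 3.84 ± 0.06 SE, adjusted p = 1.43e-05), and IFI27 rose at least 6.10-fold. Of the NF-kappaB and inflammatory cytokine genes, 12 of 34 rose (12 adjusted over the list alone; 1 fell, median log2 change 0.22, adjusted p = 0.0123, adjusted p = 0.268 with an estimated correlation). The NF-kappaB subunit RELB rose 9.11-fold and the transcription factor IRF1 1.89-fold. Of the AP-1 and immediate early genes, 15 of 28 rose and 4 fell (15 and 5 adjusted over the list alone; median log2 change 0.65, adjusted p = 0.0123, adjusted p = 0.268 with an estimated correlation). The transcription factors EGR1 and JUNB rose 11.7-fold and 5.21-fold. Autophagy genes rose at 19 of 31 members (19 adjusted over the list alone; 1 fell, median log2 change 0.49, adjusted p = 6.45e-05, adjusted p = 0.268 with an estimated correlation). The autophagy receptor SQSTM1, also called p62, rose 6.47-fold (log2 change 2.69 ± 0.08 SE, adjusted p = 5.58e-05), and WIPI1, a phosphoinositide-binding protein of early autophagosomes, rose 4.48-fold. Of the lysosomal genes, 18 of 32 rose and 3 fell (19 and 3 adjusted over the list alone; median log2 change 0.53, adjusted p = 9.59e-05, adjusted p = 0.148 with an estimated correlation). The peptidase TPP1 rose 4.91-fold and cathepsin D, CTSD, 4.51-fold.

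Several metabolic lists, ribosome biogenesis and the proteasome were lower in LN229. Glycolysis genes fell at 14 of 21 members (15 adjusted over the list alone; 1 rose, median log2 change -0.76, adjusted p = 1.62e-05, adjusted p = 0.268 with an estimated correlation). TPI1 fell 2.74-fold and PGAM1 2.43-fold. Of the genes of the TCA cycle and pyruvate entry, 14 of 20 fell (16 adjusted over the list alone; 1 rose, median log2 change -0.60, adjusted p = 2.33e-05, adjusted p = 0.296 with an estimated correlation). The pyruvate dehydrogenase subunit PDHB fell 2.58-fold and the isocitrate dehydrogenase subunit IDH3A 2.07-fold. The cholesterol synthesis genes fell at 14 of 20 members (16 adjusted over the list alone; median log2 change -0.87, adjusted p = 1.83e-05, adjusted p = 0.268 with an estimated correlation). MVD fell 2.15-fold and lanosterol synthase, LSS, 2.04-fold. Of the fatty acid synthesis genes, 12 of 16 fell and 2 rose (12 and 2 adjusted over the list alone; median log2 change -0.72, adjusted p = 0.00102, adjusted p = 0.296 with an estimated correlation). The desaturases SCD5 and FADS2 fell 1.95-fold and 2.58-fold. Of the MYC and ribosome biogenesis genes, 30 of 39 fell (34 adjusted over the list alone; 1 rose, median log2 change -0.58, adjusted p = 3.09e-11, adjusted p = 0.0636 with an estimated correlation). The small nucleolar ribonucleoproteins NOP58 and NOP56 fell 2.34-fold and 2.51-fold. Proteasome genes fell at 20 of 28 members (20 adjusted over the list alone; median log2 change -0.47, adjusted p = 3.66e-06, adjusted p = 0.268 with an estimated correlation). PSMD1 fell 1.66-fold and PSMD12 1.36-fold. Fatty acid beta-oxidation (5 of 20 up and 8 down; 5 and 8 adjusted over the list alone, median log2 change -0.09, adjusted p = 0.847, adjusted p = 0.981 with an estimated correlation, beside a mean of 0.01) and the cytosolic ribosomal proteins (5 of 68 up and 7 down; 4 and 5 adjusted over the list alone, median log2 change 0.05, adjusted p = 0.975, adjusted p = 0.981 with an estimated correlation, beside a mean of -0.09) did not pass.

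The shifts of the OXPHOS lists were small in LN229, and not every complex passed. In both lines these lists cover no mitochondrially encoded gene, since 0 of the 13 were measured. Of the complex I genes, 9 of 36 fell and 0 rose (8 fell when adjusted over the list alone; median log2 change -0.23, adjusted p = 0.00585, adjusted p = 0.341 with an estimated correlation). NDUFS5 fell 1.60-fold (log2 change -0.68 ± 0.06 SE, adjusted p = 0.0011) and NDUFAB1 1.69-fold. Of the genes of complexes II and III, 6 of 11 fell (6 adjusted over the list alone; median log2 change -0.32, adjusted p = 0.0248, adjusted p = 0.337 with an estimated correlation). Cytochrome c1, CYC1, fell 1.85-fold (log2 change -0.88 ± 0.07 SE, adjusted p = 0.000838) and UQCR10 1.75-fold at its brightest probe, while another bright probe of UQCR10 did not pass (log2 change -0.04, adjusted p = 0.87). Of the complex V genes, 9 of 19 fell (9 adjusted over the list alone; median log2 change -0.31, adjusted p = 0.00522, adjusted p = 0.341 with an estimated correlation). ATP5MC1 fell 1.52-fold and the inhibitory factor ATP5IF1 1.81-fold. Complex IV did not pass (median log2 change 0.00, adjusted p = 0.975, adjusted p = 0.981 with an estimated correlation). Of the genes on its list, 2 of 14 rose, among them COX7A2L by 1.64-fold, and 2 fell (adjusted over the list alone, 2 and 2). Among those that fell was cytochrome c, CYCS, by 1.62-fold, an electron carrier on this list that is not a complex IV subunit. The call of CYCS was lost without LN229 DMSO replicate 2 or LN229 momordicine replicate 2 (adjusted p = 0.0563 and 0.0615). Assembly factors went both ways, with 4 up, such as COX19 by 3.07-fold, and 11 down, such as PET100 by 1.87-fold, of 42 (5 and 11 adjusted over the list alone; median log2 change -0.05, adjusted p = 0.359, adjusted p = 0.848 with an estimated correlation). Mitochondrial ribosome genes fell at 27 of 77 members (27 adjusted over the list alone; 1 rose, median log2 change -0.30, adjusted p = 6.81e-06, adjusted p = 0.268 with an estimated correlation). MRPL12 fell 2.48-fold and MRPL27 2.36-fold. After quantile normalization and without the dimmest 50% of genes the calls of complexes I, II and III, and V ended, with adjusted p up to 0.255 for complex I, 0.154 for complexes II and III and 0.0969 for complex V over the settings tried. Of 10000 random lists of genes matched on signal level, 21.6% had a lower median than complex I, 24.8% than complexes II and III and 12.9% than complex V, so these 3 were not set apart from genes of like signal, against 0.310% for the mitochondrial ribosome and 0.05% for the TCA cycle.

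Apoptosis genes moved in both directions in LN229. Of the pro-apoptotic genes, 9 of 36 rose and 13 fell (10 and 14 adjusted over the list alone). The list did not pass the camera test (median log2 change -0.07, adjusted p = 0.847, adjusted p = 0.932 with an estimated correlation). Its median, mean and camera test pointed down, while the directional fry test pointed up (adjusted p = 0.0265). TNFRSF10B, the death receptor DR5, rose 2.35-fold (log2 change 1.23 ± 0.04 SE, adjusted p = 7.93e-05) and BBC3, the p53 effector PUMA, rose 2.12-fold (log2 change 1.09 ± 0.06 SE, adjusted p = 0.000302). Of the anti-apoptotic genes, 6 of 24 rose and 6 fell (7 and 6 adjusted over the list alone; median log2 change 0.00, adjusted p = 0.975, adjusted p = 0.981 with an estimated correlation), with a mean of -0.14 beside the median and fry pointing down (adjusted p = 0.0384). BIRC5 (survivin), which is also a mitosis gene, fell 46.0-fold (log2 change -5.52 ± 0.14 SE, adjusted p = 4.72e-05), and the caspase inhibitor XIAP rose 2.43-fold (log2 change 1.28 ± 0.09 SE, adjusted p = 0.000601).

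**Figure D1:**
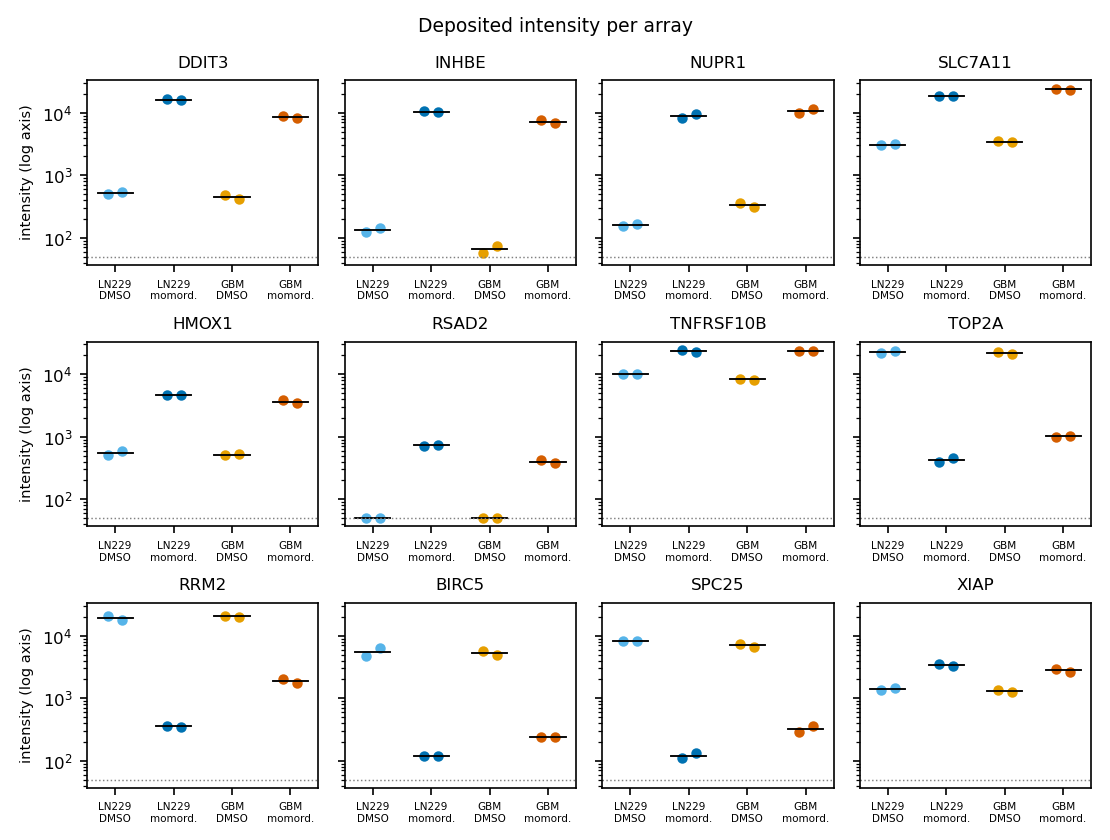
Deposited intensity of 12 genes on a log axis, 1 point per array, with a black line at the mean of the 2 arrays of each group and a dotted line at the lowest value, 50. TOP2A, RRM2, BIRC5 and SPC25 were lower and DDIT3, INHBE, NUPR1, SLC7A11, HMOX1, RSAD2, TNFRSF10B and XIAP higher on both momordicine arrays of each line.

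In GBM8401, too, genes of division were among the largest falls. DLGAP5 fell 43.2-fold (log2 change -5.43 ± 0.07 SE, adjusted p = 2.5e-05), from 10477 ± 131 to 242 ± 21.7, and the centromere histone CENPA fell 26.9-fold (log2 change -4.75 ± 0.12 SE, adjusted p = 6.78e-05). SAA1, an acute-phase protein, fell 36.9-fold (log2 change -5.21 ± 0.08 SE, adjusted p = 3.22e-05). INHBE rose 109-fold (log2 change 6.77 ± 0.15 SE, adjusted p = 4.99e-05), from 65.9 ± 12 to 7229 ± 445, and NUPR1 rose 32.3-fold (log2 change 5.01 ± 0.12 SE, adjusted p = 6e-05). The test passed 6526 genes, 3910 higher and 2616 lower, of which 1966 changed at least 2-fold.

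DRD5 rose at least 79.1-fold (log2 change 6.28 ± 0.09 SE, adjusted p = 2.84e-05) in GBM8401. LY96, a co-receptor of TLR4, rose 26.9-fold, OSCAR at least 21.5-fold and ANKFN1 30.1-fold. DEFB103B, an antimicrobial defensin with a nearly identical copy, rose 53.5-fold, and RPLP0P2, a pseudogene whose probe may read its parent gene, rose at least 20.7-fold. The controls of LY96 (52.8 ± 1.89), ANKFN1 (62.9 ± 17.6) and DEFB103B (60.6 ± 15, with 1 array at the lowest value) lay near 50, as did those of INHBE. Among the other large falls were PIMREG at 34.1-fold, ASPM at 28.8-fold, CDC20 at 22.7-fold and the mitotic kinase gene NEK2 at 22.0-fold.

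Cell cycle genes fell in GBM8401 at 65 of 66 members of the G2/M list (65 adjusted over the list alone; median log2 change -3.72, adjusted p = 9.95e-45, adjusted p = 0.0296 with an estimated correlation) and at 44 of 50 members of the G1/S list (44 adjusted over the list alone; 3 rose, median log2 change -2.23, adjusted p = 1.05e-23, adjusted p = 0.148 with an estimated correlation). HMMR fell 21.5-fold, TTK 17.0-fold, MCM10 11-fold and TYMS 6.61-fold. DNA repair genes fell at 15 of 23 members (15 adjusted over the list alone; 1 rose, median log2 change -1.08, adjusted p = 2.25e-06, adjusted p = 0.0997 with an estimated correlation). BARD1 fell 6.70-fold and BRCA1 4.64-fold.

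Of the ATF4 targets, 40 of 44 rose in GBM8401 (40 adjusted over the list alone; 1 fell, median log2 change 1.52, adjusted p = 1.68e-16, adjusted p = 0.155 with an estimated correlation). SLC7A11 rose 6.86-fold (log2 change 2.78 ± 0.04 SE, adjusted p = 2.5e-05) and DDIT3 19.3-fold (log2 change 4.27 ± 0.09 SE, adjusted p = 4.79e-05). NRF2 genes rose at 16 of 26 members (17 adjusted over the list alone; 1 fell, median log2 change 0.76, adjusted p = 4.02e-05, adjusted p = 0.155 with an estimated correlation). The aldo-keto reductase AKR1C1 rose 5.64-fold. Of the p53 target genes, 18 of 34 rose and 4 fell (19 and 5 adjusted over the list alone; median log2 change 0.53, adjusted p = 0.000226, adjusted p = 0.235 with an estimated correlation). The stress cytokine GDF15, which is also in the ATF4 list, rose 11.1-fold (log2 change 3.47 ± 0.08 SE, adjusted p = 6e-05) and SERTAD1 2.81-fold. In LN229 the p53 list had 14 genes up and 6 down of 34 (14 and 7 adjusted over the list alone) and did not pass camera (adjusted p = 0.0906, or adjusted p = 0.521 with an estimated correlation; fry pointed up, adjusted p = 0.000281), except without LN229 momordicine replicate 2 (adjusted p = 0.0372) or after quantile normalization (0.0339). Unfolded protein response genes rose at 20 of 31 members (21 adjusted over the list alone; 3 fell, median log2 change 0.59, adjusted p = 0.000226, adjusted p = 0.253 with an estimated correlation). SYVN1 rose 2.05-fold and SEL1L 3.21-fold, while the other probe of SEL1L fell (log2 change -1.17, adjusted p = 0.0107). Metallothioneins rose at 5 of 8 genes (5 adjusted over the list alone; median log2 change 0.61, adjusted p = 0.0404, adjusted p = 0.235 with an estimated correlation). MT1X rose 4.09-fold and MT1G 2.12-fold. That list's call was lost without any 1 of the 4 LN229 arrays (adjusted p up to 0.0565) and with a replicate block (0.068). MT1G lay near the lowest value in controls (54.7 ± 6.62).

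Here too, not every stress list rose. In GBM8401 heat shock genes fell at 11 of 22 members (13 adjusted over the list alone; 1 rose, median log2 change -0.40, adjusted p = 6.14e-05, adjusted p = 0.0997 with an estimated correlation). HSPA1A fell 1.73-fold and HSP90AA1 1.73-fold. The other antioxidant enzymes in GBM8401 did not pass (3 of 18 up and 3 down; 3 and 3 adjusted over the list alone, median log2 change 0.06, adjusted p = 0.944, adjusted p = 0.988 with an estimated correlation).

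Interferon-stimulated genes rose in GBM8401 at 34 of 39 members (34 adjusted over the list alone; median log2 change 1.77, adjusted p = 1.08e-14, adjusted p = 0.0997 with an estimated correlation), the antiviral synthetase OAS1 by 7.95-fold (log2 change 2.99 ± 0.05 SE, adjusted p = 3.57e-05) and RSAD2 by at least 7.91-fold. NF-kappaB and cytokine genes rose at 14 of 34 members (18 adjusted over the list alone; 1 fell, median log2 change 0.30, adjusted p = 0.00441, adjusted p = 0.235 with an estimated correlation). The chemokine CXCL2 rose 6.77-fold, and IL6 rose at least 1.71-fold from the lowest value to only 85.7 ± 4.29. AP-1 and immediate early genes rose at 16 of 28 members (16 adjusted over the list alone; 1 fell, median log2 change 0.67, adjusted p = 0.00103, adjusted p = 0.155 with an estimated correlation). EGR1 rose 15.2-fold and SPRY4, an inhibitor of growth factor signalling, 2.58-fold. Of the autophagy genes, 21 of 31 rose (22 adjusted over the list alone; 1 fell, median log2 change 0.65, adjusted p = 6.21e-06, adjusted p = 0.235 with an estimated correlation). SQSTM1 rose 7.36-fold and WIPI1 4.46-fold. Of the lysosomal genes, 21 of 32 rose (22 adjusted over the list alone; 3 fell, median log2 change 0.62, adjusted p = 7.38e-05, adjusted p = 0.155 with an estimated correlation). CTSD rose 5.05-fold and TPP1 4.61-fold. Cytosolic ribosomal proteins rose at 22 of 68 genes (25 adjusted over the list alone; 3 fell, median log2 change 0.29, adjusted p = 0.000224, adjusted p = 0.38 with an estimated correlation), with RPS12 up 1.56-fold, and this call ended after quantile normalization (adjusted p = 0.0724). RPS10 rose 1.43-fold at its brightest probe, while another probe fell (log2 change -0.78, adjusted p = 0.000388), so its direction rests on the probe.

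Of the metabolic groups in GBM8401, glycolysis genes fell at 10 of 21 members (13 adjusted over the list alone; 1 rose, median log2 change -0.51, adjusted p = 6.14e-05, adjusted p = 0.262 with an estimated correlation). PGAM1 fell 2.21-fold and TPI1 2.12-fold. TCA cycle genes fell at 8 of 20 members (9 adjusted over the list alone; median log2 change -0.29, adjusted p = 0.003, adjusted p = 0.48 with an estimated correlation). PDHB fell 1.78-fold and IDH3A 1.54-fold. Cholesterol synthesis genes fell at 11 of 20 members (11 adjusted over the list alone; 1 rose, median log2 change -0.43, adjusted p = 0.000386, adjusted p = 0.301 with an estimated correlation). Mevalonate kinase, MVK, fell 3.18-fold and LSS 1.68-fold. Fatty acid synthesis genes fell at 4 of 16 members (4 adjusted over the list alone; 2 rose, median log2 change -0.26, adjusted p = 0.0396, adjusted p = 0.538 with an estimated correlation). SCD5 fell 2.07-fold and FADS2 2.12-fold. Proteasome genes fell at 8 of 28 members (8 adjusted over the list alone; median log2 change -0.24, adjusted p = 0.000702, adjusted p = 0.38 with an estimated correlation). PSMD1 fell 1.40-fold and PSMC1 1.70-fold. The fatty acid synthesis call was lost without GBM8401 DMSO replicate 1 or GBM8401 momordicine replicate 2 (adjusted p up to 0.0924) and under dim-gene filters, in the mean of all probes and after centring on brighter genes (up to 0.184 over all settings). Fatty acid beta-oxidation in GBM8401 did not pass (8 of 20 up and 4 down; 8 and 5 adjusted over the list alone, median log2 change 0.14, adjusted p = 0.563, adjusted p = 0.812 with an estimated correlation), while the fry test pointed up (adjusted p = 0.011).

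No OXPHOS complex passed the camera test in GBM8401, while fry passed complex IV (up, adjusted p = 0.0194), complex V (down, 0.0221) and the assembly factors (up, 0.0196). Complex I had 3 genes up and 3 down of 36 (3 and 3 adjusted over the list alone; adjusted p = 0.619, or adjusted p = 0.857 with an estimated correlation), with a median of 0.01 beside a mean of -0.02. NDUFA13 rose 1.52-fold, and NDUFA11 rose 1.35-fold at its brightest probe but not in the mean of its probes (adjusted p = 0.915). Complexes II and III (3 up, 5 down; adjusted over the list alone, 3 and 5; median log2 change -0.17, adjusted p = 0.466, adjusted p = 0.752 with an estimated correlation) held CYC1 and UQCR10, which fell 1.52-fold and 1.44-fold; another bright probe of UQCR10 did not pass (log2 change -0.14, adjusted p = 0.254). Complex IV (3 up, 1 down; adjusted over the list alone, 2 and 1; median log2 change 0.20, adjusted p = 0.346, adjusted p = 0.682 with an estimated correlation) held COX7A2L and COX5A, which rose 1.66-fold and 1.72-fold; the call of COX5A was lost without GBM8401 momordicine replicate 1 (adjusted p = 0.0501). Complex V (2 up, 8 down; adjusted over the list alone, 3 and 9; median log2 change -0.15, adjusted p = 0.0869, adjusted p = 0.603 with an estimated correlation) held ATP5F1C, which fell 1.43-fold, and ATP5PD, which rose 1.18-fold but not after centring on brighter genes (adjusted p = 0.0814). Without GBM8401 DMSO replicate 2 or GBM8401 momordicine replicate 1 the complex V list passed, with adjusted p down to 0.0361. Of the 42 assembly factors, 10 rose, COX19 by 3.68-fold and SURF1 by 2.49-fold, and 5 fell (10 and 5 adjusted over the list alone; median log2 change 0.14, adjusted p = 0.382, adjusted p = 0.76 with an estimated correlation). The mitochondrial ribosome list fell (13 of 77 genes down and 7 up; adjusted over the list alone, 9 and 6; median log2 change -0.11, adjusted p = 0.0441, adjusted p = 0.603 with an estimated correlation). Of 10000 random lists matched on signal level, 38% had a lower median than complex I in GBM8401. For complexes II and III it was 13.6% and for complex V 7.48%. The share was 0.71% for the TCA cycle and 0.41% for the mitochondrial ribosome, so these 2 lists lay below genes of like signal here too. Of the mitochondrial ribosome genes, MRPL12 fell 1.77-fold and MRPL27 1.61-fold. Its call was lost without GBM8401 DMSO replicate 1 or GBM8401 momordicine replicate 2 (adjusted p up to 0.226), and also without the dimmest 25% of genes, in the mean of all probes and after centring on brighter genes.

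In GBM8401 the pro-apoptotic list had 10 genes up and 7 down of 36 (11 and 8 adjusted over the list alone; adjusted p = 0.983, or adjusted p = 0.99 with an estimated correlation), with a mean of 0.05 against a camera test that pointed down, while the directional fry test pointed up (adjusted p = 0.00241). TNFRSF10B rose 2.80-fold (log2 change 1.48 ± 0.04 SE, adjusted p = 7.52e-05) and BBC3 2.59-fold (log2 change 1.38 ± 0.06 SE, adjusted p = 0.00021). The anti-apoptotic list had 6 up and 2 down of 24 (6 and 2 adjusted over the list alone; median log2 change 0.01, adjusted p = 0.549, adjusted p = 0.652 with an estimated correlation), with fry pointing up (adjusted p = 0.011). BIRC5 fell 21.9-fold (log2 change -4.45 ± 0.14 SE, adjusted p = 0.000101) and the apoptosis inhibitor AVEN rose 2.25-fold (log2 change 1.17 ± 0.08 SE, adjusted p = 0.000742). Astrocyte and radial glia markers fell at 4 of 17 genes (4 adjusted over the list alone; median log2 change -0.30, adjusted p = 0.0107, adjusted p = 0.175 with an estimated correlation). Nestin, NES, fell 2.49-fold and the transcription factor SOX9 3.29-fold. In LN229 the astrocyte and radial glia list also fell at 4 of 17 genes, with a mean log2 change of -0.39 beside -0.40 in GBM8401. There its median was 0.00 and it did not pass camera (adjusted p = 0.122, or 0.291 with an estimated correlation). The endothelial list fell at 4 of 8 genes (4 adjusted over the list alone; median log2 change -0.31, adjusted p = 0.0333, adjusted p = 0.235 with an estimated correlation), with TEK lower by 1.93-fold and VWF by 1.26-fold, both at intensities below the median level of 287. Its call was lost without the dimmest 25% of genes, after centring on brighter genes and without GBM8401 momordicine replicate 1 (adjusted p up to 0.0761). The calls of TEK and VWF were lost without that array too (up to 0.0943 and 0.0954). Both genes were also lost without GBM8401 momordicine replicate 2, TEK without GBM8401 DMSO replicate 1 and VWF without GBM8401 DMSO replicate 2.

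**Figure D2:**
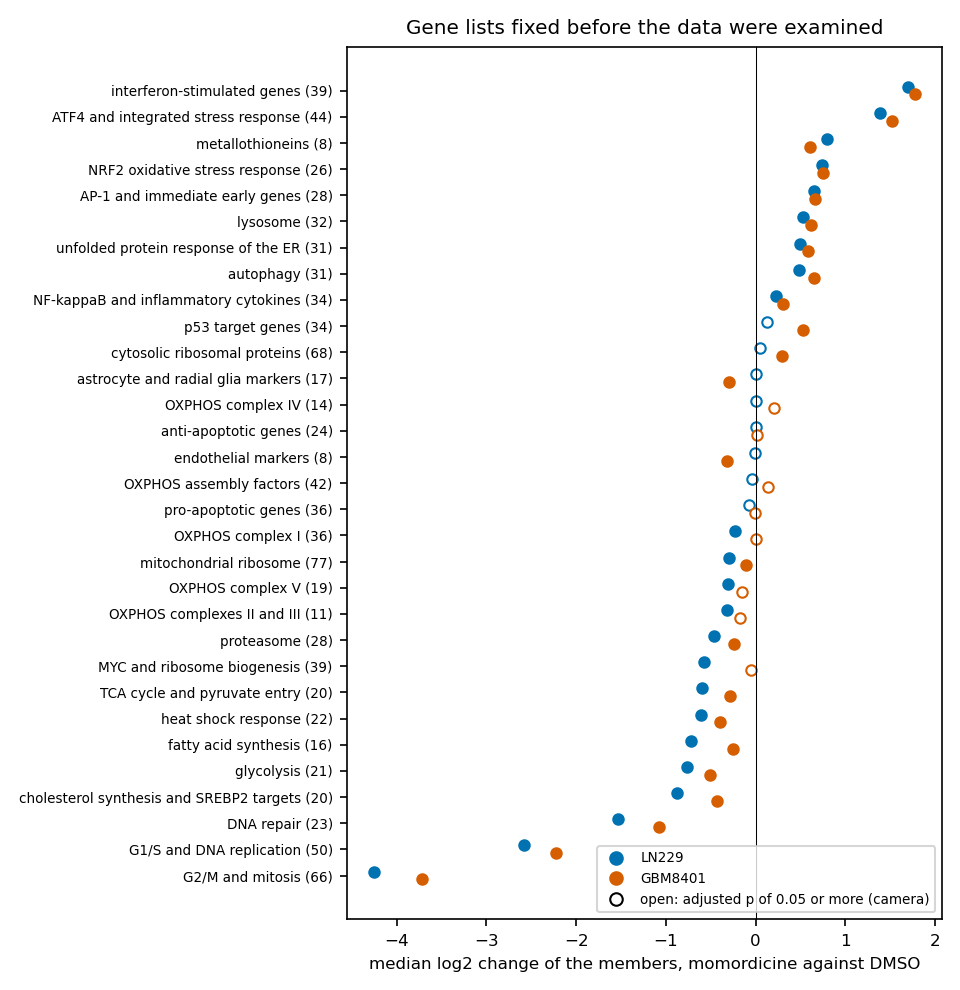
Median log2 change, momordicine against DMSO, of the members of each gene list that passed in either line or belongs to the apoptosis and OXPHOS themes, with blue points for LN229 and orange points for GBM8401; open points had a camera adjusted p of 0.05 or more. The G2/M list lies lowest, at -4.25 and -3.72, and the interferon list highest, at 1.70 and 1.77.

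The responses of the lines overlapped. Higher in both were 2789 genes, where independent calls would give 705.0, and lower in both were 2165, where 461.5 would be found. INHBE, DRD5, NUPR1, ANKFN1 and DEFB103B were among the largest mean rises over both lines, with INHBE up 92.5-fold (log2 change 6.53 ± 0.11 SE, adjusted p = 8.78e-06). DRD5 lay at the lowest value on all 4 control arrays, and INHBE, ANKFN1 and DEFB103B lay near it in the controls of at least 1 line, so these rises are not ranked. DLGAP5, PIMREG, ASPM, SAA1 and SPC25 were among the largest mean falls, with DLGAP5 lower by 60.9-fold (log2 change -5.93 ± 0.05 SE, adjusted p = 2.13e-06) and SAA1 by 41.0-fold (log2 change -5.36 ± 0.06 SE, adjusted p = 3.75e-06). On the treated LN229 arrays SAA1 (52.5 ± 3.60) and PIMREG lay near the lowest value. The mean effect passed in 8283 genes, 4515 higher and 3768 lower. Across the 9600 genes above the median level, the effects of the lines had Pearson's r of 0.922 and Spearman's rho of 0.875, and 81.9% had the same sign; genes are not independent, so no p is given. In opposite directions, 81 genes passed in both lines, and 67 of these also passed the test of the difference. With the spread taken only from the arrays compared, the genes called in both lines, same direction, were 3198 in place of 4954.

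**Figure D3:**
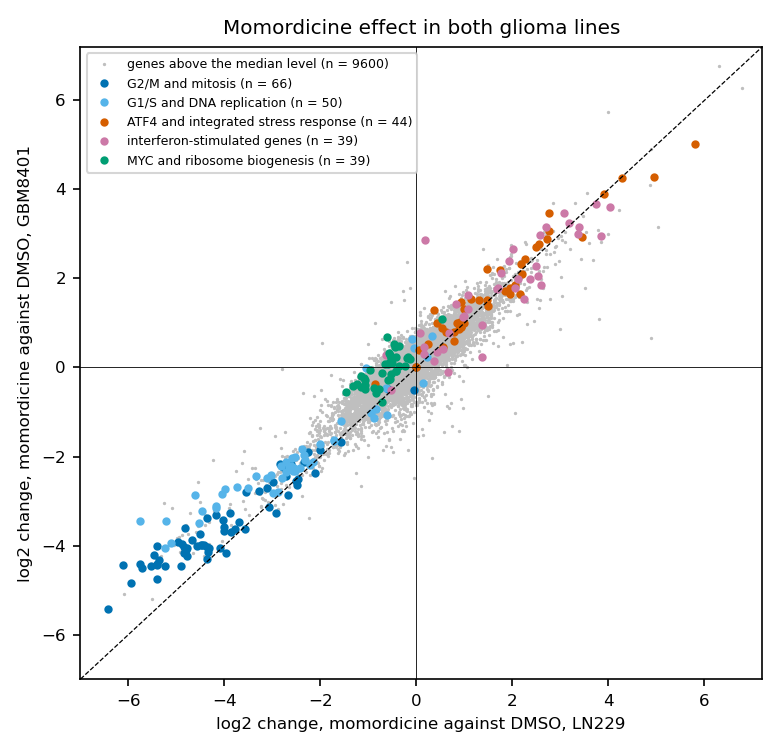
Log2 change, momordicine against DMSO, in LN229 (horizontal) and GBM8401 (vertical), 1 point per gene above the median level (grey, 9600 genes), with the members of 5 gene lists in colour and a dashed line of equal effects. Cell cycle genes lie low in both lines, ATF4 targets and interferon-stimulated genes high, and the MYC and ribosome biogenesis genes lie lower in LN229 (median -0.58) than in GBM8401 (median -0.06).

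Some genes responded differently in the lines. IL24, a cytokine of the IL-10 family, went from 1923 ± 148 to 9905 ± 1219 in GBM8401 and from 1942 ± 241 to 1695 ± 13.5 in LN229, a difference of the log2 effects of 2.55 ± 0.18 SE (adjusted p = 0.0115). The pattern recognition molecule PTX3 went from 4582 ± 227 to 1172 ± 18.2 in LN229 and from 3051 ± 7.32 to 4495 ± 710 in GBM8401 (difference 2.52 ± 0.16, adjusted p = 0.00941). RAPGEF5, an exchange factor of Ras-like GTPases, went from 106 ± 7.80 to 3165 ± 105 in LN229 and from 2286 ± 144 to 3625 ± 697 in GBM8401 (difference -4.23 ± 0.21, adjusted p = 0.00497). The treated levels of RAPGEF5 were close, so its difference mostly follows its baseline. A dimmer probe of RAPGEF5 did not pass in either line (log2 change -0.10 in LN229 and -0.23 in GBM8401, adjusted p = 0.725 and 0.298). The test of the difference passed in 589 genes, 389 with the higher effect in GBM8401 and 200 with the higher effect in LN229. With a replicate block 7 genes passed, 1 with the higher effect in GBM8401 and 6 with the higher effect in LN229, and none of the 10 named for this comparison was among them (adjusted p = 0.0939 to 0.161).

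ANKRD22 and RASD1 lay at the lowest value on all control arrays, so only their treated levels can be compared. ANKRD22 reached 2115 ± 155 in LN229 and 357 ± 26.4 in GBM8401 (difference -2.56 ± 0.12, adjusted p = 0.00445), and RASD1 reached 305 ± 57.2 in LN229 and stayed at the lowest value in GBM8401. KRTAP4-9, a hair keratin-associated gene with close relatives, lay at 812 ± 17.9 in LN229 and 147 ± 5.21 in GBM8401 controls and at the lowest value on all treated arrays, so its difference of 2.46 ± 0.05 (adjusted p = 0.000339) follows its baseline. KRTAP4-11 lay at 679 ± 157 in LN229 and 127 ± 4.18 in GBM8401 controls and at 53 ± 4.28 and 50 after treatment, so its difference follows its baseline as well. XAF1 lay near the lowest value in LN229 in both groups (51.2 ± 1.72 and 58.0 ± 8.20), and TMT1A lay at it on the treated LN229 arrays. The differences of XAF1 (2.70, adjusted p = 0.0185), KRTAP4-11 (2.31, 0.0216), TMT1A (-2.88, 0.0303), LCP1 (-2.72, 0.0197) and RASD1 (-2.57, 0.0113) were each lost when an array was left out. RASD1 was lost without LN229 DMSO replicate 2 (adjusted p = 0.0549). XAF1 was lost without either LN229 DMSO or either GBM8401 momordicine array (adjusted p up to 0.0788), and TMT1A without any array but the LN229 DMSO ones (up to 0.106). LCP1 was lost without any array but replicate 1 of the LN229 and of the GBM8401 momordicine groups (up to 0.0667). KRTAP4-11 was lost without any GBM8401 array or LN229 momordicine replicate 2 (up to 0.0767).

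Of the gene lists, MYC and ribosome biogenesis differed most between the lines. It fell in LN229, had 7 genes up and 7 down of 39 in GBM8401 (7 and 7 adjusted over the list alone; adjusted p = 0.564, or adjusted p = 0.76 with an estimated correlation), and its median difference was 0.68 (adjusted p = 5.71e-16, or adjusted p = 0.117 with an estimated correlation). MYC itself, chosen after its values were seen, fell in LN229 (log2 change -0.62, adjusted p = 0.00359) and rose in GBM8401 (0.68, adjusted p = 0.00286), a difference of 1.30 (adjusted p = 0.0149). The calls within the lines held without each array in turn, but that of the MYC difference was lost without LN229 DMSO replicate 1, LN229 DMSO replicate 2 or LN229 momordicine replicate 2 (adjusted p = 0.0565, 0.0699 and 0.0511) and with a replicate block (0.119). The G2/M genes (median difference 0.49; adjusted p = 2.8e-10, or adjusted p = 0.237 with an estimated correlation) and the G1/S genes (0.40; adjusted p = 5.59e-10, or adjusted p = 0.338 with an estimated correlation) fell less in GBM8401. The p53 targets (median difference 0.31; adjusted p = 6.5e-07, or adjusted p = 0.237 with an estimated correlation) and the cytosolic ribosomal proteins (0.27; adjusted p = 1.69e-07, or adjusted p = 0.395 with an estimated correlation) had the higher effect in GBM8401, the second not after quantile normalization (adjusted p = 0.34). So did OXPHOS complex I (0.22; adjusted p = 0.00475, or adjusted p = 0.5 with an estimated correlation), complexes II and III (0.23; adjusted p = 0.0151, or adjusted p = 0.5 with an estimated correlation) and complex V (0.20; adjusted p = 0.00887, or adjusted p = 0.503 with an estimated correlation). These OXPHOS calls ended after quantile normalization and without GBM8401 DMSO replicate 2, among other settings, with adjusted p up to 0.522, 0.518 and 0.568. In the DMSO groups the p53 list (median -0.22; adjusted p = 0.00136, or adjusted p = 0.583 with an estimated correlation), the MYC list (-0.20; adjusted p = 0.00779, or adjusted p = 0.583 with an estimated correlation) and complex I (-0.13; adjusted p = 0.0432, or adjusted p = 0.799 with an estimated correlation) were already lower in GBM8401, and these arrays enter the difference too. For the astrocyte and radial glia list the difference did not pass (adjusted p = 0.913, or adjusted p = 0.966 with an estimated correlation). Camera on the difference was chosen after seeing the data. It passed 19 of 47 lists, and 0 with an estimated correlation. For heat shock genes the estimate, -0.000118, lay below the preset 0.01, yet adjusted p for the difference rose from 0.00529 to 0.237. The loss of such calls thus cannot be put down to correlation between genes alone. The array scaling bears on this comparison: brighter genes were shifted by 0.15 on the log2 scale, and the share of called genes with the higher effect in GBM8401, 66.0%, became 50.4% after quantile normalization and 36.5% after centring on brighter genes. The count for the difference of momordicine effect between lines also changed widely when 1 array was left out, which leaves 1 array in a group. Most calls then had the higher effect in LN229 without either LN229 momordicine array or either GBM8401 DMSO array. Without any of the other arrays most still had the higher effect in GBM8401.

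Untreated, the lines differed in few genes by much. RAPGEF5 was higher in GBM8401 by 21.3-fold (log2 change 4.41 ± 0.15 SE, adjusted p = 0.00123), at 2286 ± 144 against 106 ± 7.80 in LN229. TGFBI, a matrix protein induced by TGF-beta, was higher by 15.5-fold (log2 change 3.96 ± 0.07 SE, adjusted p = 0.000202), the actin-bundling protein LCP1 by 14.2-fold, TMT1A by 13.4-fold and TRO by 11.6-fold. LN229 was higher in DEFB103B by 13.8-fold (log2 change -3.79 ± 0.17 SE, adjusted p = 0.00216), with GBM8401 controls near 50 (60.6 ± 15), MAMDC2 by 4.93-fold, KRTAP4-9 by 5.50-fold, KRTAP4-11 by 5.26-fold and the RPS19 probe by 5.40-fold. The test passed 875 genes, 392 higher in GBM8401 and 483 higher in LN229, and 200 differed at least 2-fold. RAPGEF5, TMT1A, LCP1 and the KRTAP4 genes were also named for the difference of effects, a comparison that shares the 4 DMSO arrays with this one.

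Among cell type markers, the neurofilament gene NEFL was higher in GBM8401 by 3.42-fold (log2 change 1.78 ± 0.06 SE, adjusted p = 0.00123), the keratin KRT7 by 3.58-fold (log2 change 1.84 ± 0.10 SE, adjusted p = 0.00367) and the synaptic gene SNAP25 by at least 5.29-fold, while the smooth muscle actin gene ACTA2 was lower by 1.74-fold (log2 change -0.80 ± 0.05 SE, adjusted p = 0.00523). The LN229 controls of KRT7 lay near 50 (51.0 ± 1.37). SNAP25 was lost without LN229 DMSO replicate 2 (adjusted p = 0.0557). SOX9 was higher in GBM8401 by 1.94-fold, lost without LN229 DMSO replicate 2 or either GBM8401 DMSO array (adjusted p up to 0.0884). The glutamate transporter gene SLC1A3 and TEK were higher by 2.25-fold and 2.82-fold, ESAM by 1.60-fold, and KRT18 was lower by 1.18-fold. SLC1A3 and KRT18 were lost without any 1 of the 8 arrays (adjusted p up to 0.149 and 0.191), TEK without any but GBM8401 DMSO replicate 2 (up to 0.123) and ESAM without any DMSO or GBM8401 momordicine array (up to 0.155). For GBM8401 DMSO against LN229 DMSO, the count of 875 fell to 264 without LN229 DMSO replicate 2, to 312 to 479 without any other DMSO or LN229 array, and to 48 with the spread from the 4 DMSO arrays alone. The share higher in GBM8401, 44.8%, became 60.3% after quantile normalization and 64.2% after centring on brighter genes.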

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

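The tests of array scaling, single arrays, compressed range and, for complex I, signal level were chosen only after the results were seen, as was camera on the difference between the lines. The response differed between the lines, by the test of the difference itself, in 589 genes. Of the named genes, XAF1 (difference of log2 effects 2.70), IL24 (2.55), PTX3 (2.52), KRTAP4-9 (2.46) and KRTAP4-11 (2.31) had the higher effect in GBM8401. RAPGEF5 (-4.23), TMT1A (-2.88), LCP1 (-2.72), RASD1 (-2.57) and ANKRD22 (-2.56) had the higher effect in LN229. The transcription factor gene MYC, chosen after its values were seen, had a difference of 1.30 (adjusted p = 0.0149). The calls of XAF1, KRTAP4-11, TMT1A and LCP1 were each lost without 4 to 6 of the 8 arrays in turn (adjusted p up to 0.106), that of RASD1 without LN229 DMSO replicate 2 (0.0549), and that of MYC without either LN229 DMSO array or LN229 momordicine replicate 2 (up to 0.0699). With a replicate block all 10 named genes lost the call (adjusted p = 0.0939 to 0.161), as did MYC (0.119), and 7 genes passed. The SE of the MYC difference was smaller with the block, at 0.0646 against 0.107, so a larger spread did not cause the loss for MYC. ANKRD22 and RASD1 lay at the floor on all control arrays, so their differences compare treated levels alone. KRTAP4-9 and KRTAP4-11 lay at or near the floor on all treated arrays, so theirs follow the baseline. RAPGEF5 had close treated levels in the lines, so its difference mostly follows the baseline too.

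By list, the median difference of the log2 effects, GBM8401 minus LN229, was 0.49 for G2/M and mitosis, 0.40 for G1/S and DNA replication, 0.32 for DNA repair, 0.39 for fatty acid synthesis, 0.31 for p53 targets and 0.68 for MYC and ribosome biogenesis. These 6 passed in all 18 alternatives of scaling, filtering, fit and arrays, but not with an estimated correlation (adjusted p = 0.237, 0.338, 0.237, 0.503, 0.237 and 0.117, in that order). It was 0.22 for OXPHOS complex I, 0.23 for complexes II and III, 0.20 for complex V, 0.19 for OXPHOS assembly factors, 0.20 for the mitochondrial ribosome, 0.38 for the TCA cycle, 0.27 for heat shock genes and 0.23 for the proteasome. For cholesterol synthesis it was 0.16, for cytosolic ribosomal proteins 0.27, for metallothioneins -0.40, for neuron markers -0.0058, beside a mean of -0.29, and for endothelial markers -0.16. The calls of these 13 lists ended after quantile normalization, and 0 of the 19 passed with an estimated correlation. Single arrays ended some of them too. Complex I, complex V and the assembly factors were lost without GBM8401 DMSO replicate 2 or GBM8401 momordicine replicate 1 (adjusted p up to 0.123, 0.142 and 0.119), and complexes II and III without replicate 2 of LN229 DMSO or GBM8401 DMSO (0.0892). The TCA cycle was lost without LN229 momordicine replicate 2 (0.0629), the proteasome without GBM8401 DMSO replicate 2 (0.144) and neuron markers without either of these (0.095). Metallothioneins were lost without LN229 DMSO replicate 2 or LN229 momordicine replicate 1 (0.102). Cholesterol synthesis was lost without replicate 2 of LN229 DMSO, LN229 momordicine or GBM8401 DMSO or replicate 1 of GBM8401 momordicine (0.369), and endothelial markers without any array but LN229 DMSO replicate 1 and GBM8401 DMSO replicate 2 (0.123).

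Ribosome biogenesis genes fell more in LN229 than in GBM8401, and the OXPHOS complex I genes had a smaller difference of the same sign. For ribosome biogenesis, array scaling is argued against by adjusted p = 3.3e-14 after quantile normalization, with a median difference of 0.50 (adjusted p = 6.91e-22 to 2.01e-10 over 18 alternatives), although adjusted p = 0.117 with an estimated correlation. Signal level is argued against because 100% of 10000 level-matched random lists had a lower median difference, and a single array because adjusted p stayed at or below 1.33e-11 without each array in turn. For complex I both remain open: adjusted p = 0.522 after quantile normalization (0.000122 to 0.522 over 18 alternatives, and 0.5 with an estimated correlation), and 74.1% of level-matched lists had a lower median. A candidate explanation for the ribosome biogenesis part, as a hypothesis, is the opposite change of MYC, an activator of these genes; MYC's own values do not test this.

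Mitosis genes fell less in GBM8401 than in LN229. The test of a compressed range of the GBM8401 momordicine arrays, by the ratio below, could not decide, since its outcome changed with the scaling. The SD of the log2 levels over genes above the median level was 1.89 and 1.86 on these arrays. On the LN229 momordicine arrays it was 1.88 and 1.87. These spreads, and the median G2/M difference of 0.38 after quantile normalization, argue against a narrower range of the GBM8401 momordicine arrays as a whole. The ratio of the GBM8401 to the LN229 effect was taken for genes that passed and moved at least 2-fold in the mean effect. They also lay above the median level and had an LN229 effect above a set minimum in the same direction. The 95% intervals of this ratio come from resampling genes, which are not independent, and hold no spread between arrays. As deposited, its median was 0.999 (95% interval 0.980 to 1.02) among 789 that rose and 0.836 (0.821 to 0.850) among 766 that fell. However, these medians were 0.910 and 0.903 after quantile normalization and 0.896 and 0.916 after centring on brighter genes. Of the genes that fell, the 58 of the G2/M list had 0.852 (0.836 to 0.888) as deposited. The 708 outside it had 0.830 (0.816 to 0.849). After quantile normalization these were 0.884 and 0.905, and after the centring 0.891 and 0.920. The smaller fall in GBM8401 was thus not particular to mitosis genes. Only 5 of 66 list members were at the floor on any array and the other 61 had a median difference of 0.54, so values at the floor do not carry it; array scaling is argued against by adjusted p = 3.06e-11 after quantile normalization, with a median of 0.38 (9.4e-16 to 2.46e-07 over 18 alternatives), although adjusted p = 0.237 with an estimated correlation. A weaker or later response of GBM8401 cells may account for this as well, a hypothesis not tested here.

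The 18 within-line splits of the 8 arrays are too few for a share under 0.05: the real split called 8283 genes in the mean effect, which 1 of the 18, the real one, reached, and the highest other called 589. That other split is the contrast of the difference between the lines.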

How the results depend on the processing

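With a 2-fold minimum the counts were 2260 (LN229 momordicine against DMSO), 1966 (GBM8401 momordicine against DMSO), 2015 (mean momordicine effect over both lines), 145 (difference of momordicine effect between lines), 200 (GBM8401 DMSO against LN229 DMSO) and 1511 (genes called in both lines, same direction). They were 2266, 2005, 2016, 263, 213 and 1514 with unadjusted p. At adjusted p under 0.01 they were 4526, 4046, 65 (difference), 214 (DMSO groups) and 3137 (both lines). Fewer tested genes gave more calls in the difference, 1024 and 1098 without the dimmest 25% and 50% of genes and 928 without genes at the floor, and 1329 between the DMSO groups without the dimmest 25%. With the spread from the compared arrays, which are fewer, the DMSO groups gave 48 and the overlap 3198. With a replicate block the difference gave 7 and the DMSO groups 359, against 5338 in LN229 and 4898 in GBM8401. For the MYC difference the block lowered the SE from 0.107 to 0.0646, yet adjusted p rose from 0.0149 to 0.119. A crossed block lowered the count in LN229 as well, to 5839 from 6810. A block uses up residual degrees of freedom, so its lower counts cannot show whether the effects are fragile. The cause was not tested for the other genes. Without 1 array at a time, where the lone array of a group is assumed to vary like the others, the difference gave 144 to 818 and the DMSO groups 264 to 598, both lowest without LN229 DMSO replicate 2. Of the lists, 1 in each line passed with an estimated correlation, and 40 in GBM8401 with fry. The other counts stayed within 1.5 times. Quantile normalization shared 6313 of 6810 calls in LN229, 6214 of 6526 in GBM8401, 338 of 589 in the difference and 643 of 875 between the DMSO groups. Centring on the median of all genes moved nothing, since the deposited medians are equal. Of 4089 alternative values for 180 named results, 3972 kept their direction and call, 116 lost the call and 1 reversed: RPS10 in GBM8401, at -0.13 in the mean of its probes, of which the other one fell. Signal near the floor limits the rest: both groups averaged under 100 in 289 called genes in LN229 and 246 in GBM8401. Of the 180 named results, 35 lost the call or reversed in at least 1 setting. With the spread from the compared arrays 21 calls were lost, and with a replicate block 19. Each named result whose call was lost without an array also lost it in a setting of another kind.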

Other observations

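The tests in this part were chosen after the data were seen. Genes that share a symbol prefix were tested with camera as 124 families with at least 10 members above an intensity of 200 on 2 or more arrays. A gene could meet this through its treated arrays alone. Camera set the families against all 19090 genes, of which 4012 lay at the floor on all arrays. Over all genes, 3442 rose and 3368 fell in LN229, and 3910 and 2616 in GBM8401. Genes above the median level had a median log2 change of -0.07 in LN229 and 0.10 in GBM8401. The counts below give only members called in the family's direction. Nucleoporins (NUP), which build the nuclear pore, fell at 18 of 20 in LN229 (median log2 change -1.25, adjusted p = 3.66e-08) and 13 in GBM8401 (-0.76, adjusted p = 3.54e-06). The LSM proteins of RNA decay and splicing fell at 8 of 12 in LN229 (median log2 change -0.77, adjusted p = 0.00152) and 5 in GBM8401 (-0.45, adjusted p = 0.0258), and the splicing factors of the PRPF family at 7 of 10 in LN229 (median log2 change -0.51, adjusted p = 0.00237) and 6 in GBM8401 (-0.41, adjusted p = 0.0256). Centrosomal CEP genes fell at 17 of 34 in LN229 (median log2 change -0.44, adjusted p = 0.0146) and 19 in GBM8401 (-0.41, adjusted p = 0.000746). Golgins (GOLGA), of which some have nearly identical copies, rose at 11 of 18 in LN229 (median log2 change 0.90, adjusted p = 0.00135) and 12 in GBM8401 (0.77, adjusted p = 0.000154). The VPS genes of endosomal and lysosomal sorting rose at 17 of 33 in LN229 (median log2 change 0.47, adjusted p = 0.00413) and 18 in GBM8401 (0.41, adjusted p = 0.000154). The STX syntaxins of membrane fusion rose at 7 of 13 in LN229 (median log2 change 0.42, adjusted p = 0.0359) and 9 in GBM8401 (0.49, adjusted p = 0.00458) and the TBC genes, many of them Rab GTPase-activating proteins, at 12 of 27 in LN229 (median log2 change 0.27, adjusted p = 0.0218) and 12 in GBM8401 (0.52, adjusted p = 0.00175). Zinc finger genes (ZNF) rose at 99 of 268 in LN229 (median log2 change 0.21, adjusted p = 0.00505) and 121 in GBM8401 (0.33, adjusted p = 7.22e-05). These directions were the same after quantile normalization and after centring on brighter genes, and so were the calls, except that of STX in LN229 after the centring (adjusted p = 0.0918). In all, 24 families passed in LN229 and 27 in GBM8401, and 0 in either with an estimated correlation (adjusted p = 0.608 and 0.554 for NUP). The NUP genes fell more in LN229 (median difference 0.32, adjusted p = 0.000176, 0.0327 after quantile normalization, and 0.665 with an estimated correlation).

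The arrays of the lines were close to each other, with 875 genes called between the DMSO groups. An exchange of 1 array of each line within a treatment is argued against by the lowest correlation within a group, 0.992, which lay above the highest between the lines, 0.984. An exchange of both arrays of a treatment would turn the signs of the differences, but 73.7% of the 875 genes (95% interval over genes 70.7% to 76.6%) kept their sign on the momordicine arrays; the bound for this test was revised to 50% after the value was seen, since the first, 75%, did not follow from an exchange. Related or mixed cells in the lines cannot be told apart from a like expression of unrelated lines: 0 genes lay at the floor on the 4 arrays of one line and at 500 or more on all 4 of the other, and no unrelated line or genotype was analysed here to set a bound.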
